A study of Mus musculus with 16 samples.

How the data were processed

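Liver RNA from 16 C57BL/6 mouse samples was profiled on 1-colour Affymetrix-type arrays, 8 labelled as controls and 8 labelled as a model of nonalcoholic steatohepatitis (NASH), the inflamed form of fatty liver. Per the labels' protocols, total RNA was isolated with TRIzol, checked for integrity on a Bioanalyzer and labelled with biotin by the standard Affymetrix protocol. The labels describe the samples as liver biopsies. They do not say how the NASH model was induced, and they give no scan date, batch, sex or time of collection. Samples are named here by group and by the number in their labels, so the NASH model group has samples 1a and 1b.

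The values used are the log2 values per probe set that the authors deposited for 29129 probe sets. The method that produced these log2 values is not given in the sources used here. They ran from 0.62 to 12.7, and the column medians ran from 3.52 to 3.66. The genome build of the array is not given in the sources used here, and no coordinates are reported. Of the probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several, and 9557 had none listed. Of the last, 6923 were negative-control or spike-in probe sets. These annotation symbols were kept, except that 3 list members were looked up under the older symbols of the annotation. Members of the gene lists that were absent from the table are not analysed here.

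The rules for the test, the samples, the gene lists and the named genes were fixed before the data were examined. The column medians differed by 0.14, above the limit of 0.1 set for using the values as deposited, so quantile normalization was applied over all probe sets. It changed no value by more than 0.16 on the log2 scale. For each of 19505 genes, the probe set with the highest mean over the 16 samples was used, and 55 genes had more than 1 probe set. Dim genes were not filtered. The groups were compared with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes), with the group as the only term and a two-sided moderated test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Probe sets of closely related genes, such as members of the Cyp2 families, may cross-hybridise, so their fold changes are less certain.

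The 34 gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, two-sided, with adjustment over the lists. Camera with an estimated correlation and fry were alternatives. The text names the 8 highest and 8 lowest fold changes among called genes whose groups did not overlap. It also names, for each list, the 3 called members with the largest fold changes, and the genes of the pathway in the study's title whatever their values. Other genes are named only where the text says that they were chosen after their values were seen. Predicted genes are not named.

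A background floor was set after the data were examined. It is 2.89 on the log2 scale, the 95th percentile of the values of 1412 olfactory and vomeronasal receptor genes. A group with all samples below the floor has only a bound. The fold is then given as "at least", from the brighter group's mean against the mean of the higher of the floor and each sample's own value. For genes near the floor, array signals compress differences, so such folds understate the change. The number of arrays, not a count depth, limits the precision.

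The samples are listed in the labels as separate samples, but nothing says that each came from its own animal, so p-values measure the spread between these samples. NASH model 1a and 1b were compared first. The SD of their gene-wise differences was 0.387, against 0.340 to 0.466 in the 27 other NASH model pairs, and they were kept as separate samples.

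The limma and camera steps were tested on simulated data for 19505 genes with 200 changed genes. They recovered 41.8% of genes changed by 0.5 on the log2 scale, 91.0% of those changed by 1 and 100% of those changed by 2, and 4.32% of the calls were false. The real data gave 5196 calls, and the Benjamini-Hochberg cutoff depends on the share of changed genes. These rates therefore do not give the recovery in the real data. All 10 shifted lists were recovered and 0 of 30 unshifted lists were called, with simulated genes that were independent of each other.

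The alternatives fixed beforehand were centring on array medians, cyclic loess, a filter on the dimmest 40% of genes, the mean of all probe sets of a gene, eBayes with trend and robust options, array weights, 3 treatments of NASH model 1a and 1b, the omission of each sample in turn, a replicate block and an exact permutation test of named genes. Added after seeing the data were the values as deposited, centring of the deposited values on the hybridization spike-in controls in place of quantile normalization, the omission of NASH model 2 and 7, and a clock score per sample as a covariate. The clock score is the first within-group component of the circadian clock list. Exact tests, intervals and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and the random block used statmod 1.5.0.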

Results

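Gene expression was measured in 16 mouse liver samples, 8 controls and 8 from a NASH model, with 19505 genes tested per array. The study's title concerns the stimulation of soluble guanylate cyclase (sGC), the nitric oxide receptor that makes cGMP, and its effect on liver inflammation. The samples analysed here hold no treated group, so the comparison asks how the model liver differs from the control liver. On a principal component analysis the first component held 45.3% of the variance. The 8 controls lay between -40.4 and -31.4 on it and the 8 NASH model samples between 24.2 and 49.6.

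In the NASH model livers 17 of 17 genes of recruited and lipid-associated macrophages were higher (adjusted p = 6.4e-30 for the list), and 10 of 11 male-biased liver genes (2.5e-11) and 13 of 20 fatty acid and triglyceride synthesis genes (1.6e-06) were lower. These list tests used the preset correlation. With an estimated correlation the adjusted p was 0.0012 for the macrophage list and 0.040 for each of the other 2. Mmp12, a macrophage elastase, rose 307-fold, from 3.06 ± 0.45 to 11.33 ± 0.23 (log2 intensity, SD, n = 8 per group; log2 fold change 8.26 ± 0.17 SE, adjusted p = 2.1e-17). Gpnmb, a glycoprotein of lipid-laden macrophages, rose 183-fold (7.51 ± 0.19). Other genes with the largest rises were Cyp2b9 (46.7-fold), the lysosomal proton pump subunit Atp6v0d2 (26.6-fold), the glutathione transferase Gsta2 (20.5-fold), the lectin Lgals3 (16.9-fold), the lipid receptor Trem2 (16.6-fold) and the leukocyte receptor Slamf7 (from 2.47 to 6.47). In the other direction, Hsd3b5, a male-biased steroid dehydrogenase of the liver, was 134-fold lower (-7.07 ± 0.16, adjusted p = 6.1e-17), and the fatty acid elongase Elovl3 was 55.3-fold lower (-5.79 ± 0.47).

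Further falls beyond the range of the controls were those of Moxd1 (-4.47 ± 0.70), the manganese exporter Slc30a10 (-3.73 ± 0.21), the lipogenic regulator Thrsp (-3.73 ± 0.43), the organic anion transporter Slco1a1 (-3.62 ± 0.63), Tiam2 (-3.55 ± 0.18) and the oxysterol hydroxylase Cyp7b1 (-3.47 ± 0.29). The NASH model means of Slc30a10 (2.66) and Tiam2 (2.31) lay below the floor, so background limits the sizes of their falls. Moxd1 varied within the controls, at 4.24 in control 10 and 4.42 in control 5 against 8.83 to 9.82 in the other 6. Slco1a1 varied within the model, at 2.91 in NASH model 2 and 2.82 in NASH model 7 against 6.71 to 7.71 in the other 6. The same 2 samples were lowest in Elovl3 (2.07 and 2.19, against 4.42 to 5.60) and Thrsp (3.13 and 3.64, against 5.77 to 6.30). Without them the falls still passed but were smaller, 34.7-fold in place of 55.3-fold for Elovl3, 8.36-fold in place of 13.2-fold for Thrsp and 5.75-fold in place of 12.3-fold for Slco1a1.

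Across all genes, 5196 changed, 2577 higher and 2619 lower, and 1018 of them changed at least 2-fold, 785 higher and 233 lower. For 1858 called genes the groups did not overlap, against 3.03 genes expected by chance, a share of 0.0155%. The balance of directions depended on the scaling: higher genes made up 49.6% of calls in the main analysis, 39.2% (2355 higher, 3646 lower) with arrays centred on their medians, 55.4% with values as deposited and 73.7% (3307 higher, 1179 lower) with the deposited values centred on the hybridization spike-in controls. Small counts of list members moved too: with median centring 3 NRF2 and 3 fatty acid oxidation genes were lower in place of 1 each, and with spike-in centring 1 matrix gene was lower in place of 3. With a clock score as a covariate, chosen after seeing the data, 2958 genes passed, of which 2693 were also called in the main analysis. The number changed at least 2-fold did not drop in that fit (798 higher and 261 lower), and standard errors widened, for Mmp12 from 0.17 to 0.24. Counts of higher list members dropped by over 1.5 times from 17 to 11 for NF-kB pathway genes, 14 to 9 for interferon-stimulated genes, 8 to 5 for cholangiocyte genes and 6 to 2 for female-biased genes. They dropped from 6 to 0 for clock genes, which make the score, 4 to 1 for immediate early genes, 5 to 3 for both the T, B and NK cell and the bile acid lists, and 4 to 2 for both the endothelial and the endoplasmic reticulum stress lists. Counts of lower genes dropped from 10 to 6 for drug-metabolising enzymes, 9 to 5 for hepatocyte genes, 6 to 3 for Kupffer cell genes and 4 to 2 for both acute-phase and clock genes, and rose from 2 to 5 for cholesterol synthesis genes. Other lists that moved by as much had 3 or fewer called members in that direction.

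**Figure D1:**
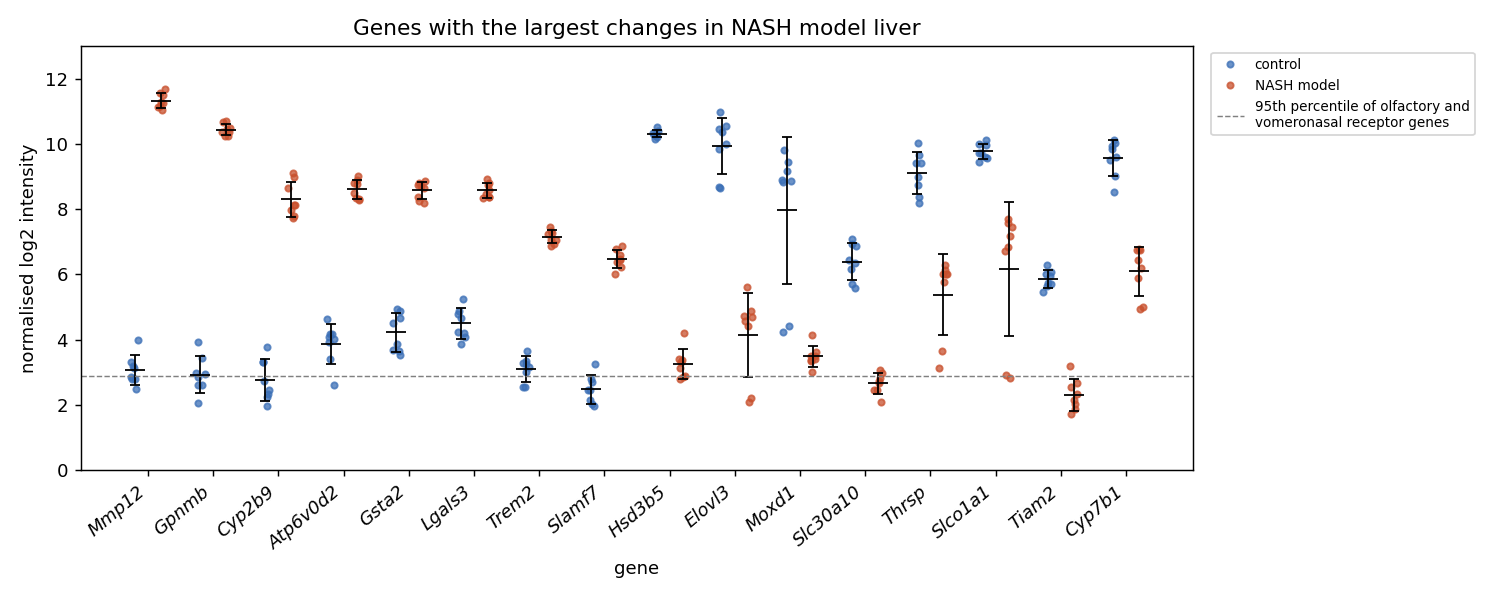
Normalised log2 intensity (y axis) of the 8 genes with the highest and the 8 with the lowest fold changes whose groups did not overlap (x axis), with 1 point per sample, 8 controls and 8 NASH model samples, bars for the mean ± SD, and a dashed line at the floor of 2.89. Mmp12 rises from a mean of 3.06 to 11.33, and Hsd3b5 falls from 10.31 to 3.24.

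Within the pathway of the title, the downstream kinase substrate and the inflammasome adaptor rose, while Rela and Il1b showed no detectable difference. The cGMP-dependent kinase Prkg1 lay near the floor in both groups. Vasp, an actin regulator phosphorylated by cGMP-dependent kinase, rose by 0.54 ± 0.13 SE on the log2 scale, from 5.51 ± 0.16 to 6.05 ± 0.34 (adjusted p = 0.0036). Its fold was similar with the clock score as a covariate, 0.57 ± 0.19, but the wider error ended the call (adjusted p = 0.053). Gucy1b1, an sGC subunit, differed by 0.33 ± 0.12 and did not pass (adjusted p = 0.053), although it passed under the 4 other scalings tried, for example at 0.47 with values as deposited (adjusted p = 0.010), with array weights, and without the dimmest 40% of genes. It also passed in the exact permutation test (adjusted p = 0.019), which was adjusted over the 106 named genes only. Calls also came without control 1 (adjusted p = 0.038), control 5 (0.011) or NASH model 5 (0.047). Gucy1b1 did not pass without NASH model 2 and 7 (0.37 ± 0.14, adjusted p = 0.067). With the clock score as a covariate its difference shrank to 0.08 ± 0.16 (adjusted p = 0.82). Prkg1 differed by 0.01 ± 0.17 (adjusted p = 0.97) and Rela, a subunit of NF-kB, by 0.05 ± 0.08 (adjusted p = 0.72). Nlrp3 was below the floor in all 16 samples, so no fold is given. Pycard, the inflammasome adaptor, rose by 1.31 ± 0.17 and Casp1, the protease it activates, by 1.29 ± 0.14. Il1b differed by 0.01 ± 0.22 (adjusted p = 0.98), and Il18 fell by 0.75 ± 0.11. Tnf rose at least 2.01-fold (adjusted p = 2.4e-08), with all controls below the floor, and the chemokine Ccl2 rose by 1.53 ± 0.15. Markers of recruited and lipid-associated macrophages rose by a median of 3.09 in the same biopsies. A change in the share of cells therefore cannot be told apart from a change within cells in these rises. The same limit holds for the inflammasome, NF-kB and chemokine lists. The other 2 genes of the title's pathway are not analysed here.

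Of 15 measured sGC and cGMP genes, 1 rose and 3 fell, and adjusted over the list alone 3 rose and 3 fell. The cGMP phosphodiesterase Pde9a fell by 1.87 ± 0.18 and the natriuretic peptide receptor Npr2 by 0.91 ± 0.16. The list did not pass as a whole (adjusted p = 0.80), and its median (0.01) and mean (-0.11) differed in sign. Without control 5, or without control 10, 3 members were higher in place of 1, as with spike-in centring.

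Of 20 inflammasome genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone). The largest rise was that of Il1rn, which encodes the antagonist of the interleukin-1 receptor, at 2.43 ± 0.21. The list was higher at adjusted p = 5.7e-04, but at adjusted p = 0.058 with an estimated correlation. Of 27 NF-kB pathway genes, 17 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 8.8e-09). Tnfaip3, a feedback inhibitor of NF-kB, rose by 2.18 ± 0.13 and the adhesion molecule Vcam1 by 1.53 ± 0.19. Chemokines and cytokines rose in 19 of 30 and fell in 1, the same counts as those adjusted over the list alone (adjusted p = 1.5e-11). Ccl3 rose by 2.29 ± 0.17 and the monocyte chemokine receptor Ccr2 by 2.12 ± 0.22, while the B cell chemokine Cxcl13 fell by 2.64 ± 0.38.

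**Figure D2:**
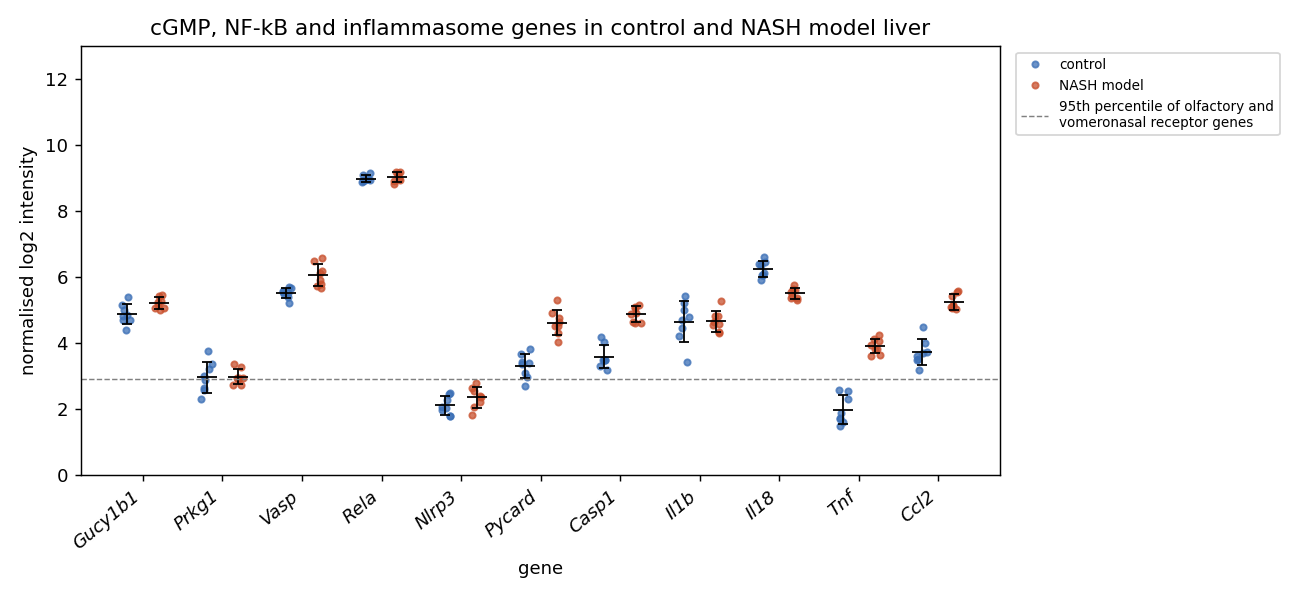
Normalised log2 intensity (y axis) of the measured genes of the title's pathway and its readouts (x axis), with 1 point per sample, 8 controls and 8 NASH model samples, bars for the mean ± SD, and a dashed line at the floor of 2.89. Pycard, Casp1, Tnf and Ccl2 are higher in every NASH model sample than in every control, Il18 is lower, and Nlrp3 stays below the line.

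Markers of recruited and lipid-associated macrophages rose in 17 of 17 measured genes, and in the same number adjusted over the list alone, with a median log2 fold change of 3.09 (adjusted p = 6.4e-30, or 0.0012 with an estimated correlation). Markers of resident Kupffer cells, the macrophages that live in the liver sinusoids, fell in 6 of 12 and rose in 1, with the same counts adjusted over the list alone. The scavenger receptor Cd163 fell by 2.84 ± 0.13, the phosphatidylserine receptor Timd4 from 4.85 ± 0.61 to 2.85 ± 0.52 and the complement component C6 from 10.76 ± 0.37 to 9.26 ± 0.62 (SD). C6 was much brighter than Cd163 and Timd4, and was lowest in NASH model 2 and 7 (8.46 and 8.08). Which cells gave its signal was not tested. The Kupffer list was lower at adjusted p = 0.027, but at adjusted p = 0.46 with an estimated correlation and at 0.059 without control 4. The call was also lost with median centring (adjusted p = 0.051), without the dimmest 40% of genes (0.088) and with the clock score (0.084).

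Antigen presentation genes were higher: of 13 dendritic cell and MHC class II genes 6 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.6e-05). H2-Aa rose by 1.78 ± 0.14, H2-Eb1 by 1.66 ± 0.15 and H2-Ab1 by 1.26 ± 0.12. Of 16 T, B and NK cell genes 5 rose and 1 fell, also adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0503). Cd8a rose by 1.02 ± 0.20 and Jchain, the joining chain of immunoglobulins, by 0.91 ± 0.25, while Cd4 fell by 1.66 ± 0.20. Without NASH model 2 and 7, 3 members were higher and Jchain did not pass (adjusted p = 0.062). Of 11 neutrophil genes 2 rose, also adjusted over the list alone, namely the receptor Csf3r (1.30 ± 0.25) and S100a8 (1.11 ± 0.31), and the list did not pass (adjusted p = 0.20). Without control 4, which had the highest S100a8 among controls, 4 neutrophil genes were higher, and without NASH model 2 and 7, 1 was, as S100a8 did not pass (0.81 ± 0.29, adjusted p = 0.058).

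Matrix genes rose broadly. Of 38 collagen and matrix genes 30 rose and 3 fell, or 31 and 3 adjusted over the list alone (adjusted p = 9.0e-20). The proteoglycan Lum rose by 3.03 ± 0.14 and the fibrillar collagen Col3a1 by 2.95 ± 0.26. Of 16 stellate cell and myofibroblast genes, markers of the liver's matrix-producing cells, 8 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.3e-05). Vim rose from 6.33 ± 0.31 to 8.83 ± 0.26 (SD), the contractile protein gene Tagln by 1.69 ± 0.17 and Pdgfrb by 1.67 ± 0.13. Of 13 cholangiocyte genes 8 rose and 0 fell, also adjusted over the list alone, at adjusted p = 1.4e-04 but adjusted p = 0.22 with an estimated correlation. They included Tspan8 (2.70 ± 0.45), Muc1 (2.28 ± 0.33) and Cd24a (1.87 ± 0.30). Without NASH model 1a and 1b, 5 of the 13 were higher. Without NASH model 2 and 7, 5 were also higher, with Tspan8 at 2.22 ± 0.41, Muc1 at 1.96 ± 0.32 and Cd24a at 1.58 ± 0.28. Endothelial genes went both ways, with 4 of 18 higher and 7 lower, also adjusted over the list alone (adjusted p = 0.47). Cd34 rose by 1.66 ± 0.23, while Kdr and Oit3 each fell by 0.70, with standard errors of 0.11 and 0.14.

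**Figure D3:**
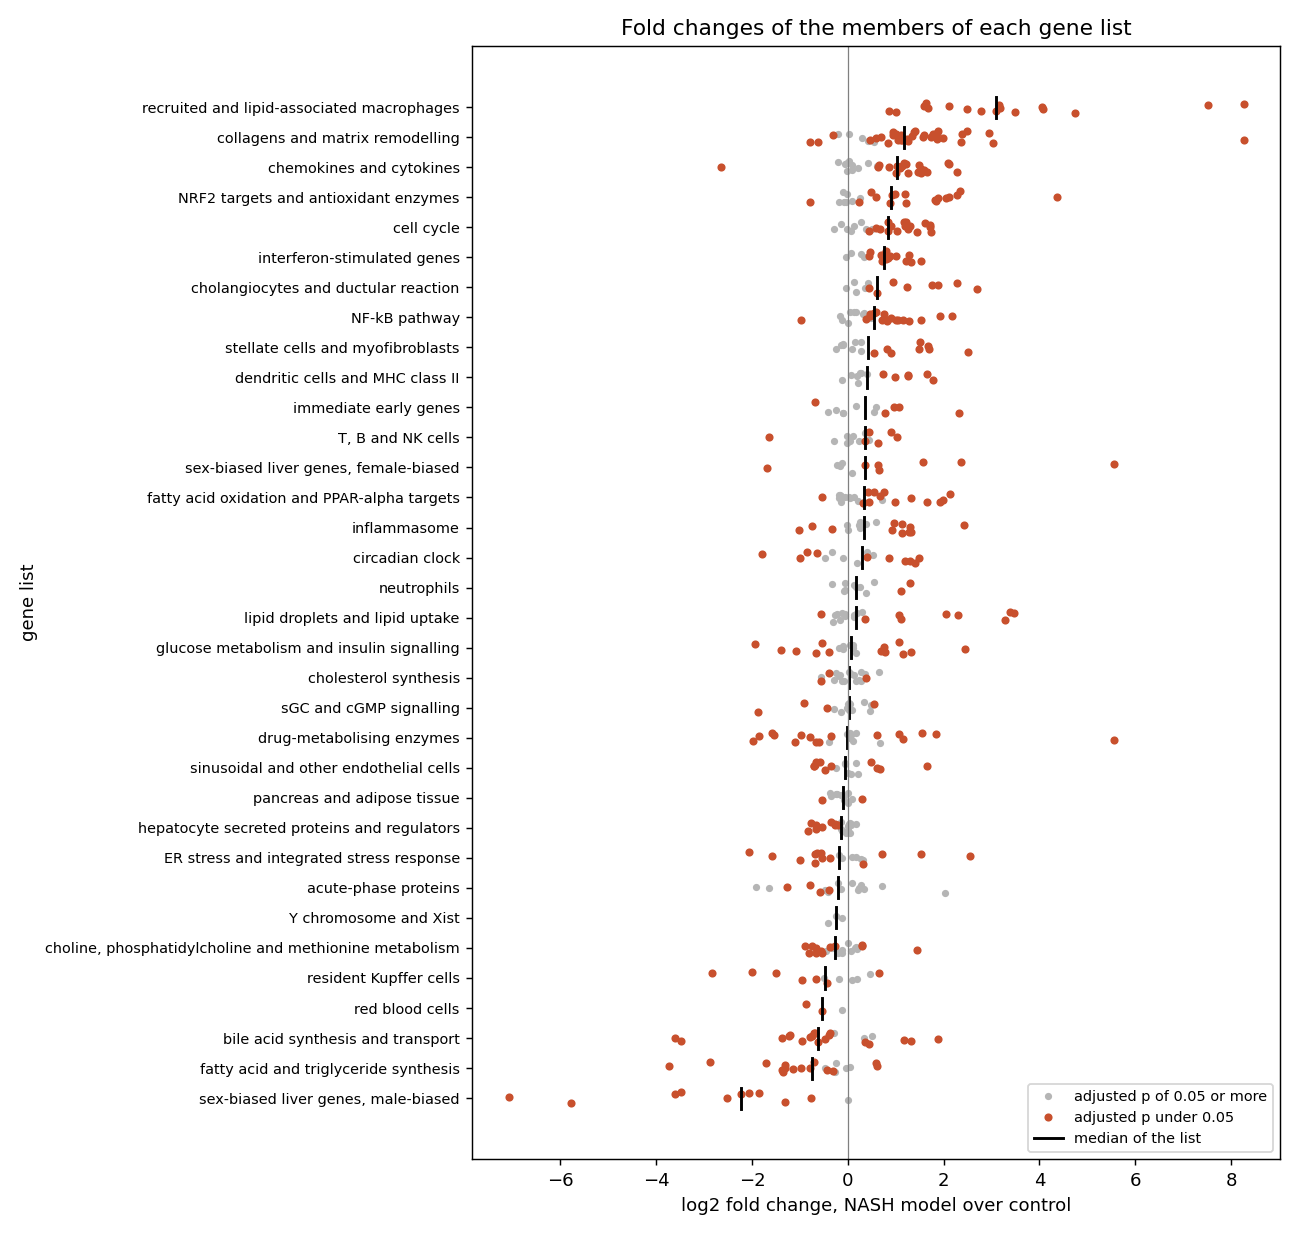
Log2 fold change of NASH model over control (x axis) for the members of the 34 gene lists (y axis), with 1 point per gene, coloured where its adjusted p is under 0.05, and a bar at each list's median. Recruited and lipid-associated macrophage genes have the highest median (3.09) and male-biased liver genes the lowest (-2.23). The list medians close to 0 change sign with the scaling in the sGC and cGMP, endothelial, cholesterol, drug-metabolising and glucose lists.

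Most genes of fatty acid synthesis fell, while a part of the genes of lipid uptake and storage rose. Of 20 fatty acid and triglyceride synthesis genes 13 fell and 2 rose, also adjusted over the list alone (adjusted p = 1.6e-06, or 0.040 with an estimated correlation). The desaturase Scd1 fell by 2.87 ± 0.19 and the malic enzyme Me1 by 1.71 ± 0.22. Of 20 lipid droplet and uptake genes 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 2.4e-04, or 0.040 with an estimated correlation). The other 11 did not pass, and the median of the list was 0.17. Lpl, lipoprotein lipase, rose by 3.46 ± 0.12, the droplet protein Cidec by 3.39 ± 0.25 and the fatty acid transporter Cd36 by 3.28 ± 0.13. Cholesterol synthesis genes showed no shift as a list, with 1 of 19 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.91). Its median was 0.03 and its mean was below 0. The members that passed were Srebf2 (0.39 ± 0.12), Pmvk (-0.56 ± 0.15) and Ebp (-0.40 ± 0.08). Srebf2 was not called with median centring (0.29, adjusted p = 0.082) or without NASH model 1a and 1b (0.28, adjusted p = 0.0998). Without NASH model 2 and 7, 4 members were higher.

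Of 25 fatty acid oxidation and PPAR-alpha genes 12 rose and 1 fell, also adjusted over the list alone, at adjusted p = 0.0096. The call did not hold with fry (adjusted p = 0.087), and the list gave adjusted p = 0.56 with an estimated correlation. Its largest rises were those of the thioesterase Acot2 (2.12 ± 0.32), the kinase Pdk4 (1.98 ± 0.41) and the hydroxylase Cyp4a14 (1.93 ± 0.60), which did not pass without NASH model 2 and 7 (1.79 ± 0.67, adjusted p = 0.069) or, with all samples, under eBayes with trend and robust options (adjusted p = 0.053). Of 24 choline, phosphatidylcholine and methionine genes 9 fell and 3 rose, or 9 and 4 adjusted over the list alone, at adjusted p = 0.022 but adjusted p = 0.23 with an estimated correlation and 0.064 without the dimmest 40% of genes. Mttp, which loads lipid onto lipoproteins, fell by 0.81 ± 0.08 and the homocysteine methyltransferase Bhmt2 by 0.90 ± 0.12, while the serine synthesis enzyme Psat1 rose by 1.43 ± 0.24. Beside these metabolic lists, 9 of 21 hepatocyte marker genes fell and 0 rose, or 9 and 1 adjusted over the list alone (adjusted p = 0.011). The hepatocyte list had a median of -0.14, but 16 of its 21 genes had mean levels of 10 or more on the log2 scale. All 5 genes below that level fell, with a mean of -0.69. The list's largest falls were those of the clotting factor F7 (-0.84 ± 0.11) and the transcription factors Foxa2 (-0.76 ± 0.14) and Cebpa (-0.67 ± 0.10).

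Bile acid genes fell in 14 of 23 and rose in 5, or 15 and 5 adjusted over the list alone, at adjusted p = 0.0047 but adjusted p = 0.36 with an estimated correlation. Besides the falls of Slco1a1 and Cyp7b1, the efflux transporter Abcc3 rose by 1.88 ± 0.17. Drug-metabolising enzymes went both ways, with 6 of 25 higher and 10 lower, or 6 and 11 adjusted over the list alone (adjusted p = 0.61). The list's median (-0.02) and mean (0.03) differed in sign. Ces2a fell by 1.97 ± 0.24 and Cyp2d9 by 1.86 ± 0.25, against the rise of Cyp2b9.

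Male-biased liver genes fell in 10 of 11, also adjusted over the list alone, with a median of -2.23 (adjusted p = 2.5e-11, or 0.040 with an estimated correlation). Female-biased genes rose in 6 of 11 and fell in 1, also adjusted over the list alone, at adjusted p = 0.025 but adjusted p = 0.16 with an estimated correlation, 0.11 without the dimmest 40% of genes and 0.063 with the clock score. Cyp2b9 and Acot3 (2.37 ± 0.68) rose, and Cyp17a1 fell by 1.69 ± 0.47. Of the 3 measured genes of the Y chromosome and Xist list, none passed, also adjusted over the list alone, and the list did not pass (adjusted p = 0.42). Without control 4, 1 of them was called lower, and the list median was -0.41 in place of -0.26.

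Antioxidant, cell cycle and interferon genes rose. Of 24 NRF2 target and antioxidant genes 16 rose and 1 fell, or 16 and 2 adjusted over the list alone (adjusted p = 2.5e-11). Besides Gsta2, the glutathione transferases Mgst3 and Gstm3 rose by 2.34 ± 0.23 and 2.29 ± 0.14. Of 25 cell cycle genes 17 rose and 0 fell, or 18 and 0 adjusted over the list alone (adjusted p = 1.3e-09). Ccnb2 rose by 1.73 ± 0.26, the replication licensing factor Mcm6 by 1.72 ± 0.18 and Mki67 by 1.71 ± 0.24. Of 18 interferon-stimulated genes 14 rose and 0 fell, or 16 and 0 adjusted over the list alone, at adjusted p = 3.6e-08 but adjusted p = 0.094 with an estimated correlation. Ifit2 rose by 1.53 ± 0.18, Usp18 by 1.32 ± 0.21 and Oas1a by 1.28 ± 0.17.

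Genes of the endoplasmic reticulum stress list went both ways, with 4 of 19 higher and 9 lower, or 5 and 9 adjusted over the list alone (adjusted p = 0.16). The stress transcription factor Atf3 rose by 2.55 ± 0.32, while Creld2 and Sdf2l1, which act in protein folding in the endoplasmic reticulum, fell by 2.07 ± 0.24 and 1.58 ± 0.20. Both varied within the controls. Creld2 was at 6.98 in control 5 and 6.71 in control 10, against 8.16 to 8.71 in the other controls. Sdf2l1 was at 6.56 and 5.98 in the same samples, against 7.16 to 7.63. Of 12 immediate early genes 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.12), with rises of Ier3 (2.31 ± 0.21), Jun (1.06 ± 0.29) and Egr1 (0.96 ± 0.30). With the clock score as a covariate their folds were no smaller, but with wider errors neither Jun (1.23 ± 0.42, adjusted p = 0.059) nor Egr1 (1.05 ± 0.44, adjusted p = 0.13) passed. Egr1 also did not pass without NASH model 1a and 1b (0.91, adjusted p = 0.061), where 2 list members were higher, or without NASH model 2 and 7 (0.95, adjusted p = 0.057).

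Glucose metabolism genes were split, with 7 of 20 higher and 6 lower, or 7 and 7 adjusted over the list alone (adjusted p = 0.44). Pkm, a pyruvate kinase, rose by 2.45 ± 0.15, while Pklr, the liver pyruvate kinase, fell by 1.93 ± 0.14 and the glucose phosphatase gene G6pc by 1.39 ± 0.25. Acute-phase genes fell in 4 of 17 and rose in 0, also adjusted over the list alone (adjusted p = 0.37). They included Saa4 (-1.27 ± 0.16), Crp (-0.79 ± 0.14) and Itih3 (-0.59 ± 0.13). This list depended on which controls were in the fit: without control 4, 3 members were higher, and without control 5 or control 10, 7 were lower. Control 5 and control 10 were the closest pair of controls (SD of gene-wise differences 0.429). Among the controls Itih3 was lowest in them, at 10.46 and 10.54, inside the NASH model range of 10.22 to 10.55. A fit without both was not run.

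Circadian clock genes changed in both directions, with 6 of 16 higher and 4 lower, or 8 and 4 adjusted over the list alone (adjusted p = 0.58). Arntl, an activator of the clock, fell by 1.79 ± 0.35, while Ciart and Usp2 rose by 1.48 ± 0.43 and 1.41 ± 0.32. The controls spread widely in these genes, with an SD of 1.07 for Arntl against 0.37 in the model. With the clock score as a covariate, which is built from these genes, Arntl (-0.45 ± 0.27, adjusted p = 0.32) and Usp2 (0.02 ± 0.13, adjusted p = 0.96) did not pass and Ciart turned to -0.35 (adjusted p = 0.30). In that fit S100a8 (0.91 ± 0.45), Srebf2 (0.30 ± 0.17), Itih3 (-0.44 ± 0.19), Slc4a1 (-0.40 ± 0.20) and Retn (-0.47 ± 0.24) also did not pass, with wider errors and somewhat smaller differences. Acot3 did not pass either, at 1.35 ± 0.94 in place of 2.37 ± 0.68. Of 3 red blood cell genes 2 fell, Alas2 by 0.87 ± 0.15 and Slc4a1 by 0.53 ± 0.14, also adjusted over the list alone (adjusted p = 0.066). With spike-in centring 1 was lower, as Slc4a1 was at -0.31 (adjusted p = 0.20). Of 12 pancreas and adipose genes 1 was called higher and 1 lower, also adjusted over the list alone (adjusted p = 0.47). Retn, an adipose gene, was at least 1.11-fold lower in the model (adjusted p = 0.019), but was not called with spike-in centring (adjusted p = 0.058) or without NASH model 2 and 7 (0.052). Prss1, the gene called higher, was below the floor in all 16 samples, so no rise is given. Its call was lost with values as deposited (adjusted p = 0.091), with median centring (0.28) and without any 1 of control 4, 5 or 6 or NASH model 4, 5 or 6.

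Of the 34 lists, 14 were higher and 6 lower with the preset correlation, and 9 were higher and 3 lower with an estimated correlation. With the preset correlation, splits of the samples with 0 called genes still gave up to 16 lists in 1 direction. The split with 16 held only 2 NASH model samples in 1 arm, so it carried part of the group difference. Splits with 4 in each arm gave at most 6. The lists that held were the NF-kB, chemokine, recruited macrophage, MHC class II, stellate, matrix, lipid droplet, NRF2 and cell cycle lists, all higher, and the fatty acid synthesis, male-biased and hepatocyte lists, all lower. Their adjusted p with an estimated correlation ran from 0.0012 (macrophages, chemokines) to 0.040 (lipid droplets, fatty acid synthesis, male-biased).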

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

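The floor, the spike-in centring, the share of receptor calls without any change and under other scalings, the level limit of 10 and the tests on sex, hepatocyte share, the samples that stand apart and the collection time were chosen after results had been seen. For 284 groups of 8 values, the highest or lowest sample was compared with the others, and 16 stood apart, against 14.2 expected by chance.

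Single NASH model samples stood apart in Hsd3b5 (4.20 in NASH model 5, against 2.80 to 3.41 in the other 7), Pde9a (4.09 in NASH model 2), Acot2 (9.55 in NASH model 2) and the mean of the inflammasome list (4.94 in NASH model 6, the lowest). Control 4 held 4 of the 16: S100a8 (4.30), Pkm (6.75), the mean of the neutrophil list (3.63), all the highest of the controls, and G6pc (10.3), the lowest. The other controls that stood apart were control 5 in Timd4 (3.52, lowest), control 1 in Psat1 (4.27, highest), control 6 in Cyp2d9 (11.51, highest) and control 9 in Atf3 (5.96, highest). Among list means, control 9 was highest for cholangiocyte genes (3.53), control 10 lowest for interferon-stimulated genes (5.02) and highest for female-biased genes (3.98), and control 7 highest for pancreas and adipose genes (2.95). Without control 4, 5122 genes were called, of which 4803 were also called with it.

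Outside the named genes, 504 of 2634 transcript clusters that had no gene symbol here differed between the groups, 254 higher and 250 lower in the NASH model. No gene is assigned to them.

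A first pattern was a lower signal of control probe sets on the NASH model arrays, by 0.19 for the background controls (exact permutation adjusted p = 9.3e-04) and by 0.12 for the ERCC controls (exact permutation adjusted p = 6.2e-04), while the poly-A controls differed by -0.29 (exact permutation adjusted p = 0.046) and the hybridization spike-ins by -0.08 (exact permutation adjusted p = 0.11). A shift that makes calls among silent genes stays open: 43 of the 1412 olfactory and vomeronasal receptor genes were called lower and 5 higher, and the share called lower depended on the scaling, from 0.850% (12 lower, 5 higher) with spike-in centring to 18.6% (262 lower, 2 higher) with median centring. The share called lower in the main analysis, 3.05% (exact 95% interval 2.21 to 4.08%), lay under the bound of 5% set beforehand, but that bound was too loose, since the threshold corresponds to an unadjusted p of 0.0133, or 0.665% per direction without any change. A shift that sets the balance of directions stays open, since centring the deposited values on the hybridization spike-in controls moved the share of higher genes by 18.3 percentage points, from 55.4 to 73.7%, and the median of all genes from -0.04 to 0.06. The mean spike-in signal was lowest in NASH model 7 (9.81) and NASH model 1a (9.87), so these arrays weigh heavily in that centring. It ran from 10.02 to 10.16 in the other NASH model arrays and from 10.01 to 10.23 in the controls. A difference in total RNA per cell between model and control liver was not tested.

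A second pattern was the fall of male-biased liver genes with the rise of Cyp2b9. Different sexes in the groups were argued against, since the largest difference among Y-linked genes was 0.41 on the log2 scale. A lower share of hepatocytes was argued against as the whole cause: the male-biased mean minus the hepatocyte mean was -2.57 (permutation p = 1e-05, the smallest that 100000 resamples can give, over genes that are not independent), and -2.10 against the 5 hepatocyte genes below a level of 10 (exact permutation p = 0.041), which fell by a mean of 0.69. The 2 samples that stand apart, NASH model 2 and 7, do not account for it either, since 10 of the 10 genes stayed lower without them. A change in hormone signalling in the model is a candidate explanation that remains untested.

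Another pattern was the change of clock genes in both directions. Across the 16 genes, which are not independent replicates, the fold changes followed the first within-group component of the same genes with r = 0.906 (bootstrap 95% interval 0.77 to 0.97, permutation p = 1e-05, the smallest possible) and Spearman's rho of 0.909 (permutation p = 0.0001, the smallest possible), or r = 0.907 with the component from controls alone and 0.479 from NASH model samples alone. A different time of collection may account for part of it, but no times are given and an effect of the model on the clock stays open. Clock scores ran from -3.82 to 2.85 in the controls and from 0.99 to 2.53 in the NASH model, so a fit with the score separates the 2 only in part.

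The group difference was set against 100 splits of the 16 samples, the real one included. For the number of genes called, chance can be excluded if the 16 samples are taken as independent. Of 100 splits 1 reached 5196, and the highest other, with 2552, held 7 of the 8 samples of 1 group in 1 arm. The splits cannot tell the model from a shift between the arrays of the groups, which stays open above. A split and its mirror count as 1, so counts in 1 direction were set against the larger direction of each other split. The same holds for higher genes (1 of 100 splits; 2577, highest other 1363), lower genes (1 of 100; 2619, highest other 1363) and genes changed at least 2-fold (1 of 100; 1018, highest other 596). For the number of lists, these splits do not exclude chance: 7 of 100 reached the 14 called higher and 62 of 100 the 6 called lower, with a highest other of 16 for both. The 6 called lower are the smaller direction of the real split, set here against the larger direction of the others. The 62 therefore does not show how often chance gives 6 lists in the smaller direction. The other splits that reached 14 held 6 or 7 of the 8 samples of 1 group in 1 arm. They carried part of the group difference, so they do not place the list counts at chance level either. Splits with 4 NASH model samples in each arm gave at most 6 lists in 1 direction.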

How the results depend on the processing

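The values as deposited, the spike-in centring, the omission of NASH model 2 and 7 and the clock score were added after seeing the data, and quantile normalization, listed beforehand as an alternative, became the main setting by rule. Of 3127 values of the 101 called named genes under the alternatives, 3094 kept their direction and side of the threshold. Another 32 lost the call in 14 genes (Prss1, Srebf2, Slc4a1, Retn, Cyp4a14, Egr1, Jchain, S100a8, Vasp, Itih3, Arntl, Usp2, Acot3 and Jun), and 1 reversed. The exact permutation test called all 101, but it was adjusted over the 106 named genes only. Most of these were named because they were called in the same values, so that result adds no independent support. Gene counts with spike-in centring were lower for falls (1179). With the clock score as a covariate, 2958 genes passed, 1606 higher and 1352 lower, and Ciart reversed (-0.35), as its own list makes the score; otherwise the cause was not tested. With an estimated correlation 9 lists were higher and 3 lower. Genes that did not pass and lay near 0 reversed: Prkg1 with median centring (-0.0627), array weights (-0.0088), and without NASH model 2 and 7 (-0.036); Rela with median centring (-0.0685); and Il1b with array weights (-0.0096), the mean of NASH model 1a and 1b (-0.0089), without both (-0.035) and without 2 and 7 (-0.0079). Leaving out each sample in turn gave 4760 to 5122 genes, 2383 to 2552 higher, 2344 to 2570 lower, 962 to 1065 changed at least 2-fold, 14 to 15 lists higher and 5 to 7 lower; Prkg1 ranged from -0.0817 to 0.1263 and Il1b from -0.1641 to 0.1228. Prss1, below the floor, lost its call without any of control 4, 5 or 6 or NASH model 4, 5 or 6 (0.25 to 0.27). Signal near the floor limits Nlrp3, Prkg1 and other dim genes: 3828 genes were below it in all samples.

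The shared numbers did not pair the samples: correlations of deviations ran from -0.05 to 0.12. With the replicate block, 3924 genes passed (2063 higher, 1861 lower), 3687 of them shared, and Il1b reversed (-0.0977). The choline and female-biased lists (adjusted p = 0.052 each), Retn (0.10) and Prss1 (0.15) were not called.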

Other observations

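Gene families, grouped by the root of their symbol and tested after the data were seen, gave further groups among 352 families with camera's preset correlation, and the 6 described here did not pass with an estimated one. Annexins, calcium-dependent membrane binding proteins, had 9 of 12 genes higher, with a median of 0.91 (adjusted p = 1.7e-08, but adjusted p = 0.088 with an estimated correlation). Their largest rises, chosen after their values were seen, were those of Anxa2 (3.29 ± 0.14 SE, log2), Anxa1 (3.19 ± 0.19) and Anxa3 (2.64 ± 0.14). Of 12 Toll-like receptors, which sense microbial products, 9 were higher, with a median of 0.94 (adjusted p = 0.075 with an estimated correlation), led by Tlr13 (3.21 ± 0.20) and Tlr1 (1.81 ± 0.20). Genes of the Ifi root, many of them interferon-inducible, had 9 of 13 higher, with a median of 1.03 (adjusted p = 0.14 with an estimated correlation).

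Large-subunit ribosomal protein genes of the Rpl root were higher in 28 of 40 and lower in 1, with a median of 0.33, but the family did not pass with an estimated correlation (adjusted p = 0.42). The median stayed above 0 under each scaling tried (0.26 to 0.44). The drug-metabolising Cyp2d family had 8 of 9 genes lower (median -1.04; adjusted p = 0.38 with an estimated correlation) and the Cyp2c family 8 of 14 (median -0.69; adjusted p = 0.54), with medians below 0 under each scaling. Cyp2c70, chosen after its value was seen, fell by 1.77 ± 0.16. Related Cyp probe sets may share signal, which a rescaling of whole arrays cannot test. Centring on array medians left 8 of 9 Cyp2d genes lower, and spike-in centring 7.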
